A study of Mus musculus with 18 samples.

How the data were processed

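Per the submitters' processing notes, total RNA from liver was prepared with a column kit, reads were aligned to GRCm39 with STAR 2.7.10b and read counts per gene were made with featureCounts of Subread 2.0.3. The deposited values are TMM-normalized counts per the labels, in 2 tables, for HFHC and CDAHFD, with 33235 genes each and 0 columns of samples outside this series. The unit of the values was taken as a signal and not as raw counts, since the deposited numbers are scaled, and limma was kept as the test although whole reads could be recovered, with edgeR and DESeq2 on those reads as alternatives. In each library every value was a whole number times 1 constant (100% of values within 0.001), which gives the reads back. The constants were set against computed factors of each diet: their largest log2 deviation was 0.0163 and 0.0143 from TMM, 0.00749 and 0.00960 from median-of-ratios and 0.131 and 0.143 from library size, on HFHC and CDAHFD.

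Mdm2 ASO replicates 6 and 7 on HFHC were identical in all 33235 genes, while any 2 other replicates of a group differed in at least 18001 genes. The 18 samples therefore counted as 17 libraries. This departs from the comparison of 4 against 4 samples set for HFHC at the start, and it was decided after the values were seen. HFHC control ASO replicates were 1, 2, 4 and 5 and Mdm2 ASO replicates 6-7, 9 and 10, and CDAHFD used replicates 1 to 5 and 6 to 10.

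Genes with a value of at least 1 in as many libraries as the smallest group were tested on log2(value + 0.5) with limma-trend, within each diet's table, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. A gene rose or fell only where it passed. The difference between diets was an interaction contrast, the CDAHFD effect minus the HFHC effect, over the genes that passed the filter in both tables, and no main effect of diet was tested because the tables were normalized separately. Mdm2 also had an exact two-sided permutation test (doubled one-sided share) of the difference of mean log2 values within each diet. The overlap of called genes was set against the product of the 2 counts over the genes tested in both, with Fisher's exact test. Counting intervals for genes with few reads are exact 95% intervals from recovered reads and cover counting error only, since PCR copies without molecular identifiers are not independent molecules.

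Gene lists were tested with camera of limma, with a preset correlation of 0.01, where at least 5 members were tested, adjusted over the lists, and again with an estimated correlation. The 37 lists cover p53 targets, lipid, bile acid, glucose and mitochondrial metabolism, matrix, inflammation, interferon, stress, cell cycle, clock and sex-biased genes, with markers of liver cell types, blood, neighbouring tissues and RNA quality. Counts adjusted over the list alone used the list's own members as the family of tests. The tests, the lists, the naming rule and most alternatives were fixed before the data were examined, apart from the merged columns. The naming rule took Mdm2, Mdm4, Trp53, Asgr1 and Asgr2, then per diet the 6 largest increases and decreases among called genes with no overlap between groups, a mean log2 of at least 1 and no model symbol, then up to 4 called members of each list by p, and for the difference the 5 called genes of smallest p in each direction. The text names a part of the members that the rule allows. Outside the rule, and chosen after their values were seen, are Cdkn1a, Ccl2 on HFHC, Perp, Fas, Ckap2, Fabp4, Uqcrc2, Bmal1, Clock, Ppp1r15a, Stat2 and Usp18, as well as Fcgr4, Lipg, Vsir, Clec4a3, Hmcn2, Opa1, Gria3 and Igsf11. Some genes of the rule are also given for the diet where the rule did not name them, chosen after their values were seen.

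Each model was tested on simulated data of the same group sizes and depth. The 100 genes changed by 2-fold and 100 by 4-fold had a mean of at least 50 reads, so genes with fewer were not tested. On HFHC, limma-trend found 84% and 100% of them and called 9 unchanged genes among 193 calls over 16821 genes. On CDAHFD it found 84% and 98% and called 7 unchanged genes among 189 calls over 17143 genes. For the difference it found 76.8% of 99 genes changed by 2-fold and 95% of those changed by 4-fold, with 4 unchanged genes among 175 calls over 16093 genes. The same simulation gave 88% and 100% with edgeR and 90% and 100% with DESeq2 on HFHC, with 15 and 32 unchanged genes called. On CDAHFD it gave 85% and 99% with edgeR and 94% and 99% with DESeq2, with 8 and 23 unchanged genes called. With the respiratory chain list raised 1.5-fold, its camera adjusted p was 6.7e-67 on HFHC and 6.2e-90 on CDAHFD. Of 32 unchanged lists, 0 passed in each. Correlated list members were not tested.

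Gene spans and exonic lengths came from GENCODE M21 on GRCm38, matched by Ensembl identifier for 32090 genes (96.6%), so no coordinates are given. Analyses ran in R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.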

Results

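Mdm2 encodes the ubiquitin ligase that marks p53 for degradation, and its transcript was the target of an antisense oligonucleotide (ASO) in the livers of wild-type mice. The oligonucleotides carried GalNAc, a sugar bound by the asialoglycoprotein receptor of hepatocytes, whose subunits are encoded by Asgr1 and Asgr2. Mice received the Mdm2 ASO or a control ASO on HFHC, a diet named only by this abbreviation here, or on CDAHFD, a choline-deficient, amino-acid-defined high-fat diet used to induce steatohepatitis. Liver mRNA was sequenced, and the deposited values were read counts per gene divided by 1 scaling factor per sample (TMM-normalized counts per the labels). Mdm2 ASO replicates 6 and 7 on HFHC held identical values in all 33235 genes and were counted as 1 library, named 6-7. The comparisons therefore used 4 control ASO and 3 Mdm2 ASO libraries on HFHC, with 17.8 to 18.8 M reads each, and 5 and 5 libraries on CDAHFD, with 22.4 to 31.5 M reads. Levels are means ± SD of the normalized counts over these libraries, fold changes are log2 ratios of Mdm2 ASO over control ASO, and adjusted p are from limma-trend unless another tool is named. Each diet's table was normalized on its own, so levels were compared within a diet.

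Mdm2 transcripts (ENSMUSG00000020184) fell on both diets by more than the spread between libraries. On HFHC, Mdm2 dropped from 945 ± 25.6 to 362 ± 58.2, which left 38.3% (log2 fold change -1.39, SE 0.11, adjusted p = 1.1e-05). The exact two-sided permutation p, taken as the doubled one-sided share, was 0.0571, the smallest that doubling allows over 35 regroupings. On CDAHFD, Mdm2 dropped from 1565 ± 87.7 to 647 ± 124, which left 41.3% (log2 fold change -1.29, SE 0.11, adjusted p = 3.1e-05). The exact two-sided permutation p, doubled in the same way, was 0.00794 over 252 regroupings. Cdkn1a, which encodes the cell cycle inhibitor p21 and is a direct target of p53, rose from 1613 ± 69.3 to 3288 ± 966 on HFHC (log2 fold change 0.98, SE 0.18, adjusted p = 0.00256). On CDAHFD, Cdkn1a rose from 2608 ± 341 to 4602 ± 1376 (log2 fold change 0.78, SE 0.17, adjusted p = 0.00873). Mdm4, the partner of Mdm2 in p53 control, rose on CDAHFD from 3187 ± 427 to 4526 ± 412 (log2 fold change 0.51, SE 0.10, adjusted p = 0.00545) but did not pass on HFHC (0.23, adjusted p = 0.0971). The 2 Mdm4 fold changes were not shown to differ (difference 0.28, adjusted p = 0.194). Trp53, the p53 transcript itself, did not pass on HFHC (-0.12, adjusted p = 0.534) or on CDAHFD (-0.08, adjusted p = 0.568). Asgr1 did not pass on HFHC (-0.22, adjusted p = 0.213) or on CDAHFD (0.28, adjusted p = 0.0696). Asgr2 did not pass on either diet (0.05, adjusted p = 0.741 and 0.27, adjusted p = 0.0901).

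**Figure D1:**
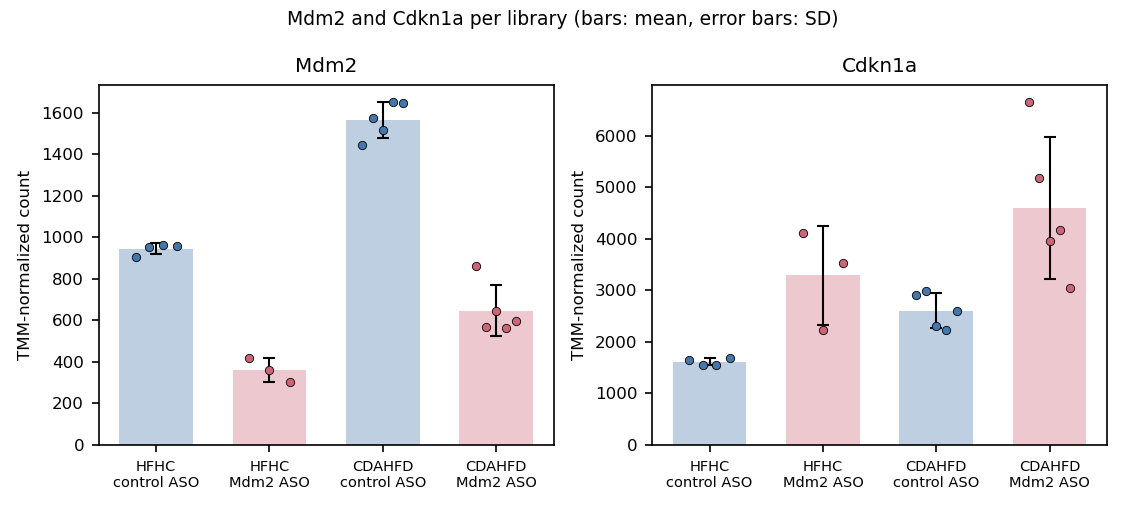
Mdm2 (left) and Cdkn1a (right) in TMM-normalized counts on the vertical axis for the 4 groups of diet and ASO, with 1 point per library, bars at the group mean and error bars of 1 SD. The Mdm2 ASO libraries held 304 to 420 counts of Mdm2 on HFHC and 564 to 861 on CDAHFD, under every control library of the same diet.

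On HFHC, markers of monocytes and neutrophils, B cells and red blood cells rose, and genes of lipid droplets, fatty acid oxidation and the respiratory chain fell. With an estimated correlation, 0 of 34 lists passed in camera (2 at an unadjusted p under 0.05). Itgax, the integrin CD11c of dendritic cells and activated macrophages, rose from 254 ± 84.9 to 5041 ± 458 (log2 fold change 4.37, SE 0.24, adjusted p = 1.3e-06). Plin2, which coats lipid droplets, fell from 18371 ± 1687 to 7602 ± 1196 (log2 fold change -1.28, SE 0.13, adjusted p = 6.9e-05). In total, 5331 of 17441 tested genes (30.6%) passed, of which 2932 rose and 2399 fell, and 7180 had an unadjusted p under 0.05. Quantile normalization turned the balance, to 2482 that rose and 3725 that fell. Of the 5331 genes, 1551 rose and 489 fell by at least 2-fold.

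Myeloid and red blood cell transcripts rose on HFHC. Of 13 tested markers of monocytes and neutrophils, the phagocytes that blood delivers to injured tissue, 12 rose and 0 fell (13 and 0 adjusted over the list alone). Their median log2 fold change was 2.69 (camera adjusted p = 2.5e-08, adjusted p = 0.403 with an estimated correlation). Csf3r, the receptor for granulocyte colony-stimulating factor, rose from 158 ± 18.5 to 1023 ± 150 (log2 fold change 2.69, SE 0.13, adjusted p = 5.9e-07). Itgam, the integrin CD11b, rose from 37.3 ± 9.51 to 501 ± 102 (log2 fold change 3.74, SE 0.22, adjusted p = 1.9e-06). S100a8, a calcium-binding protein that neutrophils carry in bulk, rose from 58.6 ± 28.5 to 625 ± 203 (log2 fold change 3.47, SE 0.34, adjusted p = 5.8e-05). All 7 tested red blood cell genes rose, also when adjusted over the list alone, with a median of 2.37 (camera adjusted p = 1.3e-04, adjusted p = 0.483 with an estimated correlation). The hemoglobin gene Hba-a2, whose reads are shared in part with its near-identical copy, rose from 288 ± 84.6 to 1544 ± 743 (log2 fold change 2.37, SE 0.32, adjusted p = 4.5e-04). Slc4a1, which encodes the anion exchanger of the red cell membrane, rose by 4.08 (SE 0.61, adjusted p = 8.9e-04).

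Several lymphocyte markers also rose on HFHC. Among 10 markers of B and plasma cells, 5 rose and none fell (5 and 0 adjusted over the list alone), with a median of 1.16 (camera adjusted p = 0.00536, adjusted p = 0.483 with an estimated correlation). Cd79b, part of the B cell receptor, rose from 18.8 ± 5.93 to 361 ± 45.3 (log2 fold change 4.28, SE 0.25, adjusted p = 2.3e-06). Ighm, the immunoglobulin M heavy chain, rose by 2.41 (SE 0.40, adjusted p = 0.00173). For T and NK cells, 5 of 16 markers rose and 0 fell, with the same counts adjusted over the list alone and a median of 0.68 (camera adjusted p = 0.00613, adjusted p = 0.483 with an estimated correlation, and 0.00134 to 0.124 over the other settings). Gzmb, a protease of cytotoxic granules, rose from 19.6 ± 10.3 to 94.9 ± 24.9 (log2 fold change 2.34, SE 0.36, adjusted p = 0.00118). Cytokine, chemokine and inflammasome genes gave 14 increases and 1 decrease among 25 (14 and 3 adjusted over the list alone), with a median of 0.63 (camera adjusted p = 0.00400, adjusted p = 0.483 with an estimated correlation). Casp1, the protease of the inflammasome, rose from 65.3 ± 5.59 to 313 ± 43.3 (log2 fold change 2.24, SE 0.14, adjusted p = 3.2e-06), and the chemokine gene Ccl4 rose by 3.22 (SE 0.30, adjusted p = 4.4e-05). Ccl2, which encodes the chemokine that draws monocytes out of the blood, was the member that fell (log2 fold change -1.10, SE 0.25, adjusted p = 0.00911). Of 27 interferon-stimulated genes, 9 rose, 2 fell and 16 did not pass (12 and 4 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 0.0319, adjusted p = 0.673 with an estimated correlation, and 0.00196 to 0.294 over the other settings). Irf7, a transcription factor of the interferon response, rose by 0.62 and the interferon-induced GTPase gene Gbp2 by 1.05, whereas Stat2, which relays interferon signals, fell by 0.49 and Usp18, which dampens them, by 0.62 (adjusted p = 0.00135, 0.00489, 0.0289 and 0.0361). Stat2 and Usp18 were chosen after their values were seen, and over the other settings their adjusted p ranged from 0.00985 to 0.0834 and from 0.0138 to 0.102. Stat2 did not pass without control replicate 4 or 5, and Usp18 did not pass without control replicate 1 or 4 or Mdm2 ASO replicate 6-7 or 10.

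Macrophage lists did not pass as lists on HFHC although single members moved far. Resident Kupffer cell markers gave 4 increases among 11 and no decrease (median 0.59, camera adjusted p = 0.113). Adgre1, the macrophage marker F4/80, rose from 377 ± 142 to 1142 ± 271 (log2 fold change 1.65, SE 0.28, adjusted p = 0.00180). Cd5l, a protein secreted by Kupffer cells, rose by 1.25 (SE 0.22, adjusted p = 0.00225). Among 14 genes of lipid-associated macrophages, the cells that surround dying fat-laden hepatocytes, 4 rose and 5 fell (6 and 5 adjusted over the list alone), with a median of 0.16 (camera adjusted p = 0.891). The lysosomal glycoprotein gene Cd68 rose from 428 ± 72.3 to 1623 ± 47.6 (log2 fold change 1.94, SE 0.12, adjusted p = 3.8e-06). Mmp12, a macrophage elastase, fell from 462 ± 51.1 to 102 ± 27.1 (log2 fold change -2.20, SE 0.17, adjusted p = 1.2e-05) and the tetraspanin gene Cd9 fell by 0.85 (SE 0.12, adjusted p = 5.6e-04). MHC class II genes, which present antigen, gave 2 increases among 7 and did not pass (median -0.20, camera adjusted p = 0.880).

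Markers of 2 sinusoidal cell types rose on HFHC, and bile duct markers fell. Of 13 markers of liver sinusoidal endothelial cells, the fenestrated lining of the sinusoids, 10 rose and none fell (11 and 0 adjusted over the list alone), with a median of 0.58 (camera adjusted p = 3.4e-05, adjusted p = 0.483 with an estimated correlation). Pecam1, an adhesion molecule that leukocytes and platelets share with endothelium, rose from 322 ± 59.9 to 1811 ± 191 (log2 fold change 2.50, SE 0.14, adjusted p = 1.8e-06). Kdr, the main receptor for vascular endothelial growth factor, rose by 0.88 (SE 0.11, adjusted p = 2.4e-04). Hepatic stellate cells, the vitamin A-storing pericytes of the liver, had 9 of 13 markers higher and none lower, with the same counts adjusted over the list alone and a median of 0.68 (camera adjusted p = 7.5e-04, adjusted p = 0.483 with an estimated correlation). Rgs5, a regulator of G-protein signals in pericytes, rose from 1043 ± 117 to 1925 ± 103 (log2 fold change 0.89, SE 0.10, adjusted p = 1.2e-04), and the secreted matrix proteins encoded by Ecm1 and Reln rose by 0.77 (SE 0.09) and 0.86 (SE 0.11), with adjusted p = 2.4e-04 and 3.3e-04. Cholangiocytes line the bile ducts, and 6 of their 12 markers fell while none rose (9 and 0 adjusted over the list alone), with a median of -1.26 (camera adjusted p = 0.00137, adjusted p = 0.483 with an estimated correlation). Krt23, a keratin of ductular cells, fell from 114 ± 21.8 to 18.6 ± 4.89 (log2 fold change -2.60, SE 0.24, adjusted p = 3.6e-05). Cftr, the chloride channel of bile ducts, fell by 2.48 (SE 0.51, adjusted p = 0.00557). The 32 genes of extracellular matrix and fibrosis gave 5 increases and 5 decreases, with a median of 0.04 and a mean of -0.07, and the test, which pointed up, did not pass (camera adjusted p = 0.891). Tgfb1, which encodes the main fibrogenic cytokine, rose from 244 ± 34.1 to 1123 ± 103 (log2 fold change 2.21, SE 0.12, adjusted p = 1.4e-06).

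Targets of p53 rose as a list on HFHC, beside a rise in cell cycle genes. Of 35 p53 target genes, 15 rose, 2 fell and 18 did not pass (16 and 3 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 0.00442, adjusted p = 0.483 with an estimated correlation). Pmaip1, which encodes the pro-apoptotic protein NOXA, rose from 50.8 ± 15.0 to 231 ± 32.8 (log2 fold change 2.20, SE 0.22, adjusted p = 6.2e-05). Phlda3, a repressor of Akt signaling, rose from 185 ± 52.1 to 589 ± 79.1 (log2 fold change 1.70, SE 0.20, adjusted p = 2.3e-04). Ccng1, the p53-induced cyclin G1, rose by 0.62 (SE 0.08, adjusted p = 4.1e-04). The 2 members that fell were Perp, a desmosome protein (-0.59, adjusted p = 8.9e-04). Fas, the death receptor (-0.36, adjusted p = 0.0135). Cell cycle genes had 19 increases among 28 and no decrease (21 and 0 adjusted over the list alone), with a median of 0.91 (camera adjusted p = 6.5e-08, adjusted p = 0.483 with an estimated correlation). Mki67, a marker of dividing cells, rose from 191 ± 45.6 to 580 ± 68.5 (log2 fold change 1.62, SE 0.17, adjusted p = 1.0e-04). Mcm3, part of the helicase that opens replication origins, rose by 1.70 (SE 0.13, adjusted p = 1.3e-05).

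Genes of lipid storage, oxidation, synthesis and export fell on HFHC. Of 28 genes of fatty acid oxidation and PPAR alpha targets, 20 fell and none rose (23 and 0 adjusted over the list alone), with a median of -0.47 (camera adjusted p = 2.7e-09, adjusted p = 0.403 with an estimated correlation). Acot1, an acyl-CoA thioesterase induced by PPAR alpha, fell from 1238 ± 87.5 to 571 ± 7.25 (log2 fold change -1.11, SE 0.08, adjusted p = 5.4e-06). Crat and Etfdh, enzymes of mitochondrial fat oxidation, fell by 0.89 (SE 0.07) and 0.52 (SE 0.07), with adjusted p = 1.9e-05 and 6.4e-04. The lipid droplet and PPAR gamma target list had 11 decreases and 3 increases among 18 genes (12 and 3 adjusted over the list alone), with a median of -0.66 (camera adjusted p = 0.00349, adjusted p = 0.483 with an estimated correlation). Plin5, a droplet coat protein of oxidative tissue, fell from 1982 ± 104 to 1153 ± 165 (log2 fold change -0.79, SE 0.10, adjusted p = 3.3e-04). Pparg, the adipogenic receptor itself, rose from 442 ± 19.6 to 904 ± 58.1 (log2 fold change 1.03, SE 0.08, adjusted p = 1.0e-05). Fatty acid and triglyceride synthesis lost 9 of 23 transcripts and gained none (10 and 1 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 0.00400, adjusted p = 0.673 with an estimated correlation, and 2.9e-05 to 0.0676 over the other settings). Fasn, the fatty acid synthase, fell from 3658 ± 306 to 1826 ± 451 (log2 fold change -1.03, SE 0.15, adjusted p = 8.5e-04). Mlxipl, which encodes the carbohydrate-responsive factor ChREBP, fell by 0.80 (SE 0.10, adjusted p = 3.7e-04). Among 26 genes of VLDL secretion, 10 fell and 2 rose (11 and 2 adjusted over the list alone), with a median of -0.34 (camera adjusted p = 0.00349, adjusted p = 0.483 with an estimated correlation, and 8.7e-04 to 0.115 over the other settings). Mttp, which loads lipid onto apolipoprotein B, fell by 0.38 (SE 0.07, adjusted p = 0.00311). Cideb, needed for large VLDL particles, fell by 0.62 (SE 0.10, adjusted p = 0.00120).

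Bile acid genes gave 11 decreases and 3 increases among 26 on HFHC (13 and 3 adjusted over the list alone), with a median of -0.245 (camera adjusted p = 0.0246, adjusted p = 0.606 with an estimated correlation, and 0.00674 to 0.307 over the other settings). Abcb4 and Abcb11, which pump phospholipid and bile salts into bile, fell by 0.77 (SE 0.09) and 0.78 (SE 0.15), with adjusted p = 2.1e-04 and 0.00438, whereas the uptake carrier gene Slco1a1 rose by 3.37 (SE 0.72, adjusted p = 0.00666). Cholesterol synthesis and uptake genes gave 3 increases and 2 decreases among 25 and did not pass (median 0.27, camera adjusted p = 0.252).

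Nuclear genes of the respiratory chain fell on HFHC, as did the transcripts that mitochondria make themselves. Of 38 nuclear genes of oxidative phosphorylation, 26 fell and none rose (31 and 0 adjusted over the list alone), with a median of -0.39 (camera adjusted p = 4.2e-10, adjusted p = 0.483 with an estimated correlation). Ndufa1, a subunit of complex I, fell by 0.71 (SE 0.07, adjusted p = 5.4e-05). Cox7c, a subunit of complex IV, fell by 0.67 (SE 0.10, adjusted p = 6.4e-04). Of 13 mitochondrially encoded transcripts, which also serve as a measure of RNA quality, 10 fell and none rose (11 and 0 adjusted over the list alone), with a median of -0.94 (camera adjusted p = 3.4e-05, adjusted p = 0.483 with an estimated correlation). ND5, the mitochondrial complex I subunit 5, fell from 109760 ± 4774 to 53590 ± 5481 (log2 fold change -1.04, SE 0.19, adjusted p = 0.00274). NRF2 and xenobiotic genes, which detoxify reactive compounds, had 13 decreases and 1 increase among 20 (15 and 1 adjusted over the list alone), with a median of -0.59 (camera adjusted p = 1.7e-04, adjusted p = 0.483 with an estimated correlation). Gstm3, a glutathione transferase with close paralogs, fell from 2103 ± 151 to 563 ± 229 (SE of the log2 fold change 0.25, adjusted p = 2.9e-04). Hmox1, the heme oxygenase that macrophages use to degrade hemoglobin, rose from 725 ± 92.6 to 3814 ± 906 (log2 fold change 2.38, SE 0.15, adjusted p = 3.9e-06). Endoplasmic reticulum stress genes gave 7 decreases and 2 increases among 20 (8 and 2 adjusted over the list alone), with a median of -0.20 (camera adjusted p = 0.0484, adjusted p = 0.673 with an estimated correlation, and 0.00918 to 0.325 over the other settings). Pdia4, a protein-folding enzyme, fell by 0.48, whereas the stress-induced genes Atf3 and Ppp1r15a rose by 0.88 and 0.76 (adjusted p = 0.00138, 0.00466 and 0.00766).

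Pericentral hepatocytes surround the central vein, and 4 of their 14 markers fell on HFHC while none rose, with the same counts adjusted over the list alone and a median of -0.52 (camera adjusted p = 0.00856, adjusted p = 0.483 with an estimated correlation, and 0.00144 to 0.129 over the other settings). Glul, the glutamine synthetase of this zone, fell from 38711 ± 2324 to 17698 ± 4166 (log2 fold change -1.16, SE 0.17, adjusted p = 9.6e-04), and the Wnt target gene Axin2 fell by 1.49 (SE 0.36, adjusted p = 0.0120). General hepatocyte genes, such as those of plasma proteins, gave 2 decreases among 18 and did not pass (median -0.20, camera adjusted p = 0.0675).

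The largest increases on HFHC were in genes that the control libraries barely expressed. Fcrl5, an Fc receptor-like gene of B cells, rose from 4.58 ± 5.05 to 2567 ± 107 (log2 fold change 9.83, SE 0.90, adjusted p = 3.5e-05). Itgad, an integrin of tissue macrophages, rose from 6.60 ± 8.35 to 1091 ± 50.4 (log2 fold change 7.94, SE 0.69, adjusted p = 2.5e-05). Klra17, a lectin-like receptor of myeloid cells with many paralogs, rose by 7.90 (SE 0.81), Scel, an epithelial envelope protein, by 7.69 (SE 0.66), Htra4, a secreted serine protease, by 7.64 (SE 0.73) and Negr1, a neural adhesion molecule, by 7.45 (SE 0.57), with adjusted p = 7.7e-05, 2.4e-05, 4.8e-05 and 1.2e-05. Ephb2, a receptor for membrane-bound ephrins, fell from 491 ± 144 to 22.2 ± 9.63 (log2 fold change -4.49, SE 0.33, adjusted p = 8.4e-06). Cyp21a1, a steroid hydroxylase with a pseudogene copy, fell by 4.22, Rbm24, an RNA-binding protein of muscle, by 3.97 and Folh1, a carboxypeptidase, by 3.94 (adjusted p = 0.00790, 0.00322 and 0.00153). Fabp3, the fatty acid carrier of heart, held 145 reads in the control libraries and 3 in the Mdm2 ASO libraries, a 39.9-fold ratio with a 95% counting interval of 13.4 to 196 (adjusted p = 0.00193). Mir6358, a microRNA gene inside a host gene, held 72 and 3 reads, a 19.8-fold ratio with an interval of 6.51 to 98.3 (adjusted p = 0.00255). At the preset correlation of camera 21 of the 34 lists passed. Other groupings of the 7 libraries gave up to 25. Member counts were not set against the 30.6% of all genes that passed.

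On CDAHFD, 19 of 35 p53 target genes rose, and 14 of 27 interferon-stimulated, 11 of 28 cell cycle and 8 of 18 lipid droplet genes fell. These 4 lists passed at the preset correlation of camera and did not with an estimated correlation (adjusted p = 0.0988 for p53 targets and 0.414 for the other 3). Psrc1, a spindle protein induced by p53, rose from 81.6 ± 31.8 to 569 ± 169 (log2 fold change 2.83, SE 0.26, adjusted p = 3.9e-05). Rsad2, the antiviral enzyme viperin, fell from 582 ± 129 to 250 ± 75.5 (log2 fold change -1.24, SE 0.19, adjusted p = 0.00126). In total, 2181 of 16803 tested genes (13.0%) passed, of which 1028 rose and 1153 fell, and 4734 had an unadjusted p under 0.05. The count fell to 1232 without control replicate 2, 1426 without Mdm2 ASO replicate 8 and 1424 with eBayes without a trend. At least 2-fold changes were found in 212 genes that rose and 182 that fell.

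Among 35 p53 target genes on CDAHFD, 19 rose, 1 fell and 15 did not pass (20 and 1 adjusted over the list alone), with a median of 0.67 (camera adjusted p = 6.4e-09, adjusted p = 0.0988 with an estimated correlation). Phlda3 rose from 331 ± 87.9 to 1059 ± 274 (log2 fold change 1.67, SE 0.20, adjusted p = 2.6e-04). Pidd1, a death domain protein that p53 induces, rose from 147 ± 13.9 to 342 ± 44.7 (log2 fold change 1.21, SE 0.12, adjusted p = 1.1e-04). Ccng1 rose by 0.83 (SE 0.14, adjusted p = 0.00192). Pmaip1, which rose on HFHC, did not pass (-0.18, adjusted p = 0.793) and differed between diets by -2.38 (adjusted p = 0.00239). The member that fell was Ckap2, a spindle-associated protein of dividing cells (log2 fold change -1.65, SE 0.32, adjusted p = 0.00516). Cell cycle genes gave 11 decreases and no increase among 28 (18 and 0 adjusted over the list alone), with a median of -0.88 (camera adjusted p = 2.0e-08, adjusted p = 0.414 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, fell from 266 ± 145 to 56.0 ± 20.5 (log2 fold change -2.13, SE 0.36, adjusted p = 0.00211). The mitotic cyclin gene Ccnb1 fell by 2.10 (SE 0.37, adjusted p = 0.00301) and Mki67 fell from 383 ± 102 to 175 ± 83.9 (log2 fold change -1.23, SE 0.29, adjusted p = 0.0151).

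Interferon-stimulated genes fell on CDAHFD, with 14 decreases and no increase among 27 (18 and 0 adjusted over the list alone) and a median of -0.445 (camera adjusted p = 2.0e-08, adjusted p = 0.414 with an estimated correlation). Cmpk2, a mitochondrial nucleotide kinase next to Rsad2 in the interferon response, fell from 294 ± 32.8 to 151 ± 12.5 (log2 fold change -0.95, SE 0.12, adjusted p = 4.1e-04). Ifit2, an RNA-binding antiviral protein, fell from 172 ± 29.1 to 76.8 ± 23.8 (log2 fold change -1.20, SE 0.21, adjusted p = 0.00274). Irf7 fell by 0.46 (adjusted p = 0.0180), Gbp2 by 0.81 (adjusted p = 0.0263) and Usp18 by 0.81 (adjusted p = 0.00832). Cytokine, chemokine and inflammasome genes gave 5 decreases and no increase among 25 (9 and 0 adjusted over the list alone), with a median of -0.35 (camera adjusted p = 8.8e-04, adjusted p = 0.670 with an estimated correlation). Icam1, an adhesion molecule for leukocytes, fell from 622 ± 99.7 to 363 ± 73.0 (log2 fold change -0.79, SE 0.14, adjusted p = 0.00348). Ccl2 fell from 203 ± 73.6 to 81.3 ± 42.1 (log2 fold change -1.45, SE 0.37, adjusted p = 0.0195). Acute phase genes, which hepatocytes secrete in inflammation, gave 5 decreases and no increase among 22, with the same counts adjusted over the list alone and a median of -0.165 (camera adjusted p = 0.0362, adjusted p = 0.670 with an estimated correlation, and 0.00553 to 0.120 over the other settings). Cp, the copper carrier ceruloplasmin, fell from 30660 ± 1640 to 17388 ± 1635 (log2 fold change -0.82, SE 0.10, adjusted p = 2.7e-04). Lbp, which binds bacterial lipopolysaccharide, and Lcn2, an iron-scavenging lipocalin, fell by 0.79 (SE 0.13) and 1.02 (SE 0.22), with adjusted p = 0.00163 and 0.00984. Lipid-associated macrophage genes gave 2 decreases and no increase among 14, with the same counts adjusted over the list alone and a median of -0.525 (camera adjusted p = 0.0139, adjusted p = 0.670 with an estimated correlation, and 1.1e-06 to 0.0973 over the other settings). The 2 were Cd9 (-1.06, adjusted p = 0.0120) and the lipoprotein lipase gene Lpl (from 2356 ± 341 to 1337 ± 834, adjusted p = 0.0330), and Cd5l of Kupffer cells fell by 0.84 (SE 0.21, adjusted p = 0.0174). Monocyte and neutrophil markers did not pass, with 0 increases and 0 decreases among 12 by limma and 0 with an unadjusted p under 0.05 (median -0.25, camera adjusted p = 0.313).

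Lipid droplet and PPAR gamma target genes fell on CDAHFD, with 8 decreases and no increase among 18 (8 and 1 adjusted over the list alone) and a median of -0.32 (camera adjusted p = 6.9e-04, adjusted p = 0.414 with an estimated correlation). Plin2 fell from 34653 ± 5619 to 20586 ± 3158 (log2 fold change -0.75, SE 0.14, adjusted p = 0.00324) and Plin5 from 3707 ± 366 to 2384 ± 362 (log2 fold change -0.64, SE 0.11, adjusted p = 0.00191). Cd36, a fatty acid uptake receptor, fell from 5215 ± 568 to 2933 ± 602 (log2 fold change -0.85, SE 0.13, adjusted p = 0.00115). Hsd17b13, a droplet enzyme of hepatocytes, fell by 0.68 (SE 0.11, adjusted p = 0.00134). Of 28 genes of fatty acid oxidation and PPAR alpha targets, 2 fell and none rose, with the same counts adjusted over the list alone and a median of -0.30 (camera adjusted p = 4.6e-04, adjusted p = 0.670 with an estimated correlation). These were Etfdh (-0.65, adjusted p = 0.0196) and Pdk4, a kinase that holds back glucose oxidation in fasting (-1.32, adjusted p = 0.0263). Fatty acid and triglyceride synthesis genes gave 3 increases and 3 decreases among 23 and did not pass (median 0.03, camera adjusted p = 0.996). Fasn did not pass (-0.11, adjusted p = 0.670). Bile acid genes did not pass either, with 4 increases and 3 decreases among 26 (median -0.15, camera adjusted p = 0.533), although Abcb4 fell by 0.43 (adjusted p = 0.0404) and Slco1a1 rose by 1.10 (adjusted p = 0.00179).

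Nuclear genes of the respiratory chain rose on CDAHFD, with 12 increases and 1 decrease among 38 (14 and 1 adjusted over the list alone) and a median of 0.15 (camera adjusted p = 0.00268, adjusted p = 0.670 with an estimated correlation). Ndufa5 of complex I rose from 2475 ± 191 to 3634 ± 507 (log2 fold change 0.55, SE 0.10, adjusted p = 0.00366), and Cox5b of complex IV rose by 0.38 (SE 0.08, adjusted p = 0.00572). Uqcrc2, a core subunit of complex III, fell by 0.50 (SE 0.13, adjusted p = 0.0203). Mitochondrially encoded transcripts had 1 increase among 13, while the other 12 did not pass, with the same count adjusted over the list alone and a median of 0.35 (camera adjusted p = 0.0421, adjusted p = 0.789 with an estimated correlation, and 0.00167 to 0.247 over the other settings). That gene was ND3, subunit 3 of complex I, which rose from 232 ± 70.0 to 523 ± 149 (log2 fold change 1.16, SE 0.21, adjusted p = 0.00369). NRF2 and xenobiotic genes gave 2 increases and 5 decreases among 20 and did not pass (median -0.24, camera adjusted p = 0.129). Hmox1 fell from 934 ± 203 to 555 ± 148 (log2 fold change -0.76, SE 0.19, adjusted p = 0.0181) and Gstm3 by 1.03 (SE 0.23, adjusted p = 0.0113).

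Male-biased liver genes, which growth hormone pulses maintain in male mice, rose on CDAHFD, with 8 increases and no decrease among 19 (10 and 0 adjusted over the list alone) and a median of 0.46 (camera adjusted p = 9.1e-07, adjusted p = 0.414 with an estimated correlation). Hsd3b5, a steroid dehydrogenase, rose from 50.7 ± 43.7 to 637 ± 276 (log2 fold change 3.87, SE 0.54, adjusted p = 7.2e-04). The major urinary protein Mup12, whose family shares reads, rose by 2.01 (SE 0.26, adjusted p = 4.5e-04). Hsd3b5 rose on HFHC by 5.37 (adjusted p = 0.00198). Core clock genes, which keep daily rhythms, gave 7 increases and 2 decreases among 14 (9 and 5 adjusted over the list alone), with a median of 0.81 (camera adjusted p = 0.0277, adjusted p = 0.414 with an estimated correlation, and 0.00447 to 0.0518 over the other settings). Dbp, a clock output factor that peaks in the daytime, rose from 1242 ± 411 to 3214 ± 964 (log2 fold change 1.39, SE 0.25, adjusted p = 0.00326). The related factor Tef rose by 1.00 (SE 0.15, adjusted p = 0.00126) and the repressor Ciart rose by 2.44 (SE 0.42, adjusted p = 0.00250). Bmal1 and Clock, which encode the activators of the clock, fell by 1.10 (SE 0.26) and 0.42 (SE 0.12), with adjusted p = 0.0148 and 0.0349. Both were chosen after their values were seen, and over the other settings their adjusted p ranged from 0.00241 to 0.0534 and from 0.0178 to 0.0865. Clock did not pass without control replicate 1, 2, 3 or 4 or Mdm2 ASO replicate 7, 8 or 9. Clock genes depend on the time of day at collection, which was not analysed here, so a difference in collection time between the groups is not excluded.

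On CDAHFD, hepatic stellate cells had 3 markers higher among 13 and none lower, with the same counts adjusted over the list alone and a median of 0.23 (camera adjusted p = 0.0277, adjusted p = 0.670 with an estimated correlation, and 0.00475 to 0.129 over the other settings), Ecm1 among them (log2 fold change 0.61, SE 0.11, adjusted p = 0.00422). Of 13 sinusoidal endothelial markers, 1 rose, the scavenger receptor gene Stab1 (0.51, adjusted p = 0.0401), and none fell (4 and 0 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.0123, adjusted p = 0.670 with an estimated correlation, and 0.00335 to 0.0669 over the other settings). Cholangiocyte markers had 0 of 12 pass by limma, though 7 had an unadjusted p under 0.05 and 4 rose adjusted over the list alone, and the median was 0.92 (camera adjusted p = 0.0140, adjusted p = 0.670 with an estimated correlation, and 1.6e-04 to 0.109 over the other settings). General hepatocyte genes gave 1 increase among 18, with a median of -0.05 under a test that pointed up and did not pass (camera adjusted p = 0.843). B and plasma cell markers did not pass (median 0.49, camera adjusted p = 0.0993), although Ighm rose by 0.90 (SE 0.26, adjusted p = 0.0345).

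Among the largest increases on CDAHFD, Sec14l5, a lipid-binding protein, rose from 9.22 ± 5.39 to 109 ± 38.7 (log2 fold change 3.54, SE 0.39, adjusted p = 1.9e-04). Mup11, another major urinary protein, rose from 695 ± 541 to 5281 ± 3157 (log2 fold change 3.19, SE 0.58, adjusted p = 0.00338) and Pierce1, a protein of cilia, rose from 6.85 ± 3.37 to 63.7 ± 20.9 (log2 fold change 3.18, SE 0.38, adjusted p = 2.7e-04). Ppef2, a phosphatase of the retina, held 3 reads in the control libraries and 35 in the Mdm2 ASO libraries, a 13.4-fold ratio with a 95% counting interval of 4.22 to 68.0 (adjusted p = 0.00522). Fcrl5 held 1 read in the control libraries and 216 in the Mdm2 ASO libraries, a 248-fold ratio with an interval of 44.0 to 9829 (adjusted p = 0.00717). Eme1, a subunit of a DNA repair nuclease, fell by 3.16, the cadherin gene Cdh18 by 2.98, the sperm gene Smcp by 2.95 and Mab21l4, of epidermal differentiation, by 2.66 (adjusted p = 0.00974, 0.0219, 0.0144 and 0.0124). The mucin gene Muc13 held 29 reads in the control libraries and 2 in the Mdm2 ASO libraries, a 12.6-fold ratio with an interval of 3.20 to 109 (adjusted p = 0.0137). The homeobox gene Hesx1 held 26 and 3, a 7.56-fold ratio with an interval of 2.32 to 39.0 (adjusted p = 0.0253). Of 33 lists tested on CDAHFD, 15 passed with the preset correlation of camera and 0 with an estimated correlation (3 at an unadjusted p under 0.05). Other groupings of the 10 libraries gave up to 21 passing lists.

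**Figure D2:**
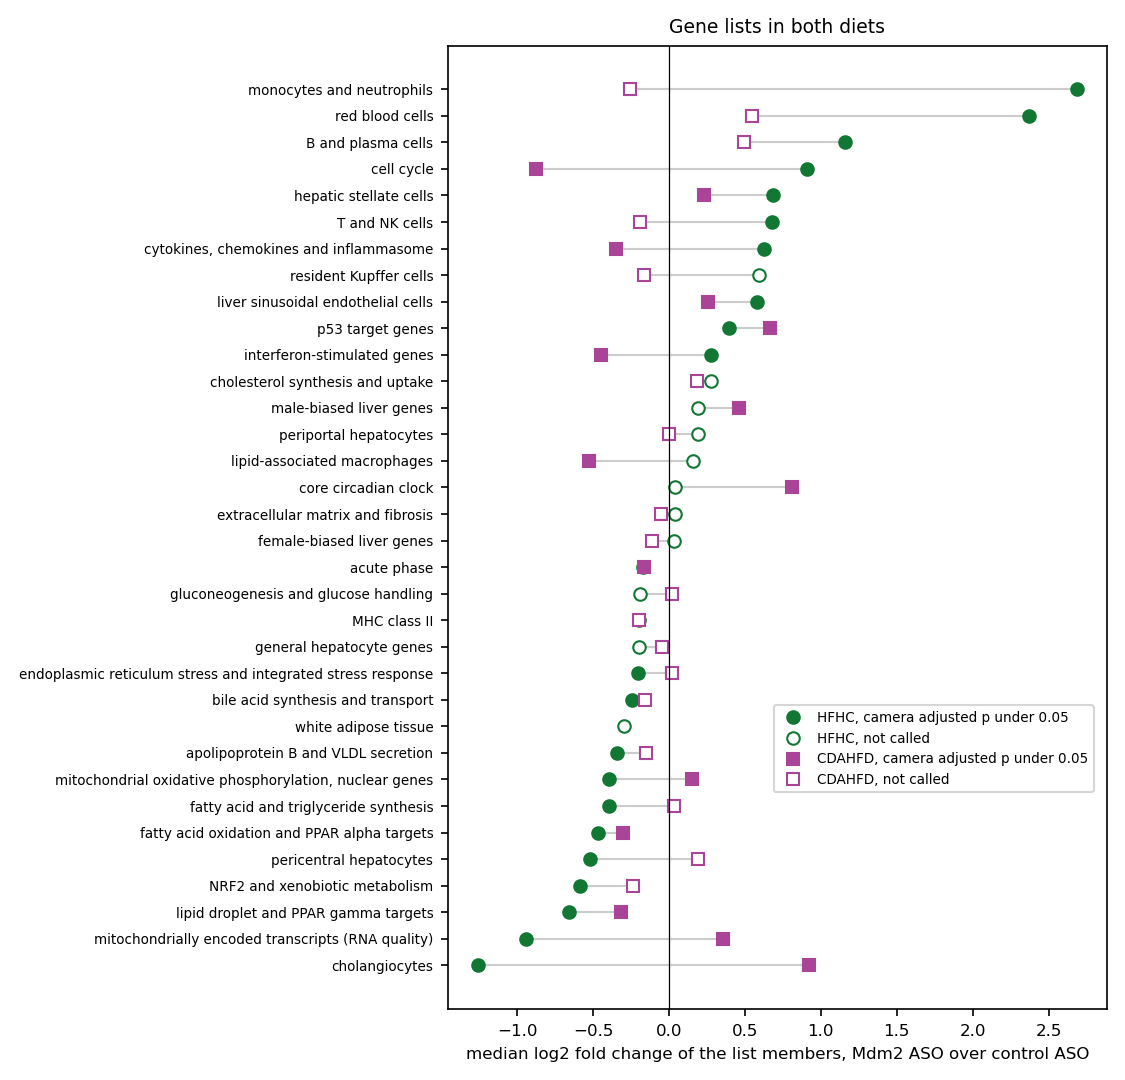
Median log2 fold change of each gene list's tested members, Mdm2 ASO over control ASO, on the horizontal axis, for HFHC (circles) and CDAHFD (squares), with filled symbols for camera adjusted p under 0.05 at the preset correlation and 1 list per line. Monocyte and neutrophil markers stood at 2.69 on HFHC and -0.25 on CDAHFD, and p53 targets at 0.39 and 0.67.

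Mdm2 fell on both diets and p53 target genes such as Cdkn1a rose, while monocyte and neutrophil, cytokine, interferon-stimulated, cell cycle and respiratory chain genes differed between the diets. With an estimated correlation, 0 of 33 list differences passed in camera (2 at an unadjusted p under 0.05). Itgam rose on HFHC and did not pass on CDAHFD (-0.24, adjusted p = 0.618), and its 2 fold changes differed by -3.98 (SE 0.41, adjusted p = 1.8e-06). Hmox1 rose on HFHC and fell on CDAHFD, a difference of -3.14 (SE 0.29, adjusted p = 5.7e-07). Differences are given as the CDAHFD fold change minus the HFHC fold change, tested as an interaction in limma. Of 16333 genes tested, 3832 (23.5%) passed, 1606 more positive and 2226 more negative on CDAHFD, and 5719 had an unadjusted p under 0.05. Quantile normalization turned this balance, with 2466 more positive and 1957 more negative. Across genes, the fold changes of the 2 diets had a Pearson r of 0.0907 and a Spearman rho of 0.0652, and r was 0.0509 without CDAHFD Mdm2 ASO replicate 7. Chance was not excluded for r, since 7 of 35 groupings of the HFHC libraries reached its size. Mdm2 itself did not pass in this test (difference 0.10, adjusted p = 0.705), nor did Cdkn1a (-0.20, adjusted p = 0.647) or the p53 list, whose median was 0.24, mean -0.02 and camera adjusted p = 0.167.

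**Figure D3:**
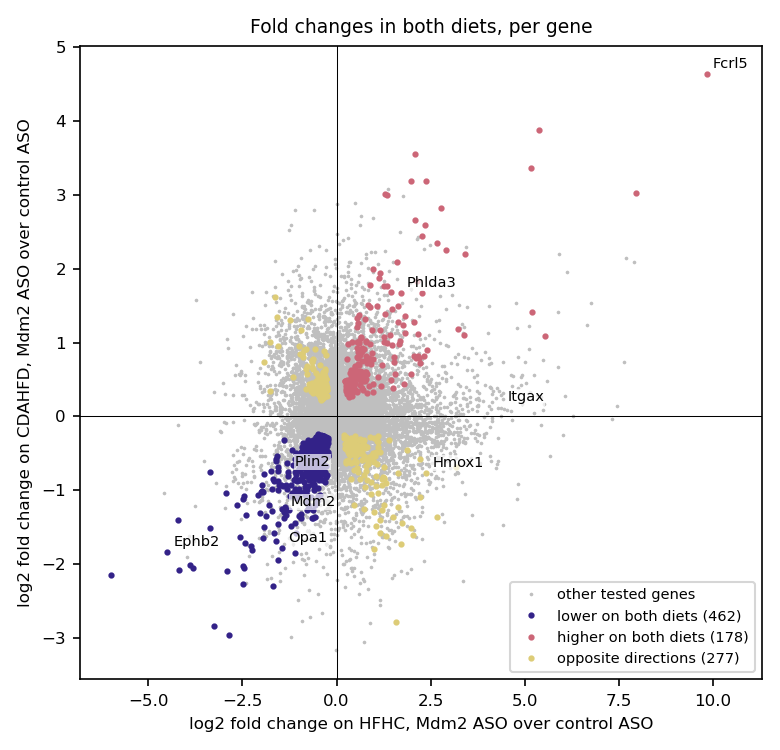
Log2 fold change of each gene tested in both diets, HFHC on the horizontal and CDAHFD on the vertical axis, Mdm2 ASO over control ASO, with 1 point per gene and color for genes that passed on both diets. In this plot 462 genes fell on both diets, 178 rose on both and 277 passed in opposite directions.

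Cell cycle genes had 25 of 28 more negative on CDAHFD and none more positive (25 and 0 adjusted over the list alone), a median difference of -1.94 (camera adjusted p = 3.8e-13, adjusted p = 0.357 with an estimated correlation). Mki67, which rose on HFHC and fell on CDAHFD, differed by -2.85 (SE 0.42, adjusted p = 7.8e-05). Monocyte and neutrophil markers had 10 of 12 more negative and none more positive, with the same counts adjusted over the list alone and a median of -3.03 (camera adjusted p = 1.1e-07, adjusted p = 0.357 with an estimated correlation). Interferon-stimulated genes had 14 more negative and 1 more positive among 27 (16 and 1 adjusted over the list alone), with a median of -0.655 (camera adjusted p = 4.3e-06, adjusted p = 0.465 with an estimated correlation). Cytokine genes had 14 of 25 more negative and none more positive (15 and 0 adjusted over the list alone), with a median of -1.32 (camera adjusted p = 2.2e-05, adjusted p = 0.547 with an estimated correlation). Red blood cell genes had 1 of 6 more negative (3 adjusted over the list alone), with a median of -1.63 (camera adjusted p = 0.0389, adjusted p = 0.547 with an estimated correlation, and 0.00440 to 0.130 over the other settings). T and NK cell markers had 1 of 16 more negative, the same count adjusted over the list alone, with a median of -1.04 (camera adjusted p = 0.0446, adjusted p = 0.713 with an estimated correlation, and 0.00953 to 0.143 over the other settings).

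Nuclear respiratory chain genes were more positive on CDAHFD in 26 of 38 cases and more negative in none (30 and 0 adjusted over the list alone), with a median difference of 0.50 (camera adjusted p = 3.8e-13, adjusted p = 0.465 with an estimated correlation). Cox5b fell by 0.45 on HFHC and rose by 0.38 on CDAHFD, a difference of 0.83 (SE 0.11, adjusted p = 3.3e-05). Mitochondrially encoded transcripts had 8 of 13 more positive and none more negative (13 and 0 adjusted over the list alone), with a median of 1.10 (camera adjusted p = 2.0e-05, adjusted p = 0.547 with an estimated correlation). Cholangiocyte markers had 8 of 12 more positive and none more negative (10 and 0 adjusted over the list alone), with a median of 1.91 (camera adjusted p = 3.4e-05, adjusted p = 0.547 with an estimated correlation). Krt23 differed by 3.17 (SE 0.47, adjusted p = 8.2e-05). Pericentral markers had 7 of 14 more positive and none more negative (8 and 0 adjusted over the list alone), with a median of 0.76 (camera adjusted p = 9.5e-04, adjusted p = 0.465 with an estimated correlation). Glul differed by 1.10 (SE 0.21, adjusted p = 7.1e-04). Male-biased genes had 5 more positive and 1 more negative among 19 (6 and 1 adjusted over the list alone), with a median of 0.84 (camera adjusted p = 0.00223, adjusted p = 0.547 with an estimated correlation). NRF2 and xenobiotic genes had 8 more positive and 1 more negative among 20 (11 and 1 adjusted over the list alone), with a median of 0.69 (camera adjusted p = 0.00550, adjusted p = 0.547 with an estimated correlation). Fatty acid and triglyceride synthesis genes had 3 of 23 more positive, the same count adjusted over the list alone, with a median of 0.15 (camera adjusted p = 0.0446, adjusted p = 0.720 with an estimated correlation, and 5.1e-04 to 0.366 over the other settings). Fatty acid oxidation genes had 4 of 28 more positive (3 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.0446, adjusted p = 0.751 with an estimated correlation, and 0.00488 to 0.604 over the other settings).

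Lyn, Ptpn6, Ptpn1, Stap1 and Cd47 held the smallest p among genes more negative on CDAHFD. Lyn, a Src-family kinase of myeloid and B cells, rose by 2.46 on HFHC and did not pass on CDAHFD (-0.19, adjusted p = 0.342), a difference of -2.64 (SE 0.17, adjusted p = 5.0e-08). Ptpn6, the phosphatase SHP-1 that restrains leukocyte receptors, differed by -2.35 (SE 0.16) and Ptpn1, the phosphatase PTP1B that dampens insulin signaling, by -2.17 (SE 0.14), each with adjusted p = 5.0e-08. Stap1, an adaptor of B cell and macrophage signaling, rose by 2.21 on HFHC and fell by 0.58 on CDAHFD, and Cd47, the surface protein that holds off phagocytes, rose by 1.08 and fell by 0.33 (differences -2.79 and -1.41, each with adjusted p = 5.0e-08). In the other direction, Lars2, the mitochondrial leucyl-tRNA synthetase, fell by 1.77 on HFHC and rose by 0.34 on CDAHFD, a difference of 2.11 (SE 0.26, adjusted p = 9.9e-06). Notum, a pericentral inhibitor of Wnt proteins, fell by 0.81 and rose by 0.65, a difference of 1.46 (SE 0.18, adjusted p = 1.0e-05). Adcy6, an adenylate cyclase, and Gstt2, a glutathione transferase, differed by 1.16 (SE 0.15) and 0.98 (SE 0.13), with adjusted p = 1.5e-05 and 1.7e-05. Cyp2u1, a fatty acid hydroxylase, fell by 1.73 on HFHC and did not pass on CDAHFD (0.30, adjusted p = 0.244), a difference of 2.03 (SE 0.26, adjusted p = 1.7e-05).

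Genes that fell on both diets outnumbered the chance overlap, with 462 shared where 167 were expected from the 2 counts (ratio 2.76, Fisher's exact two-sided p = 5.3e-110, with genes taken as independent). Plin2, Plin5, Cd36, Cp and Ephb2 were among them, and the median genomic span of the 462 was 28.4 kb. Genes that rose on both diets numbered 178 where 176 were expected (ratio 1.01, Fisher's exact two-sided p = 0.830), with Phlda3, Psrc1, Ccng1 and Cdkn1a among them. Genes that rose on HFHC and fell on CDAHFD numbered 143 where 198 were expected (ratio 0.722, Fisher's exact two-sided p = 4.5e-06), with Hmox1, Pparg and Mki67 among them. Genes that fell on HFHC and rose on CDAHFD numbered 134 where 148 were expected (ratio 0.904, Fisher's exact two-sided p = 0.199), with Notum among them. At the preset correlation of camera 14 of the 33 lists passed. Other groupings of the libraries gave up to 24 passing lists.

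**Figure D4:**
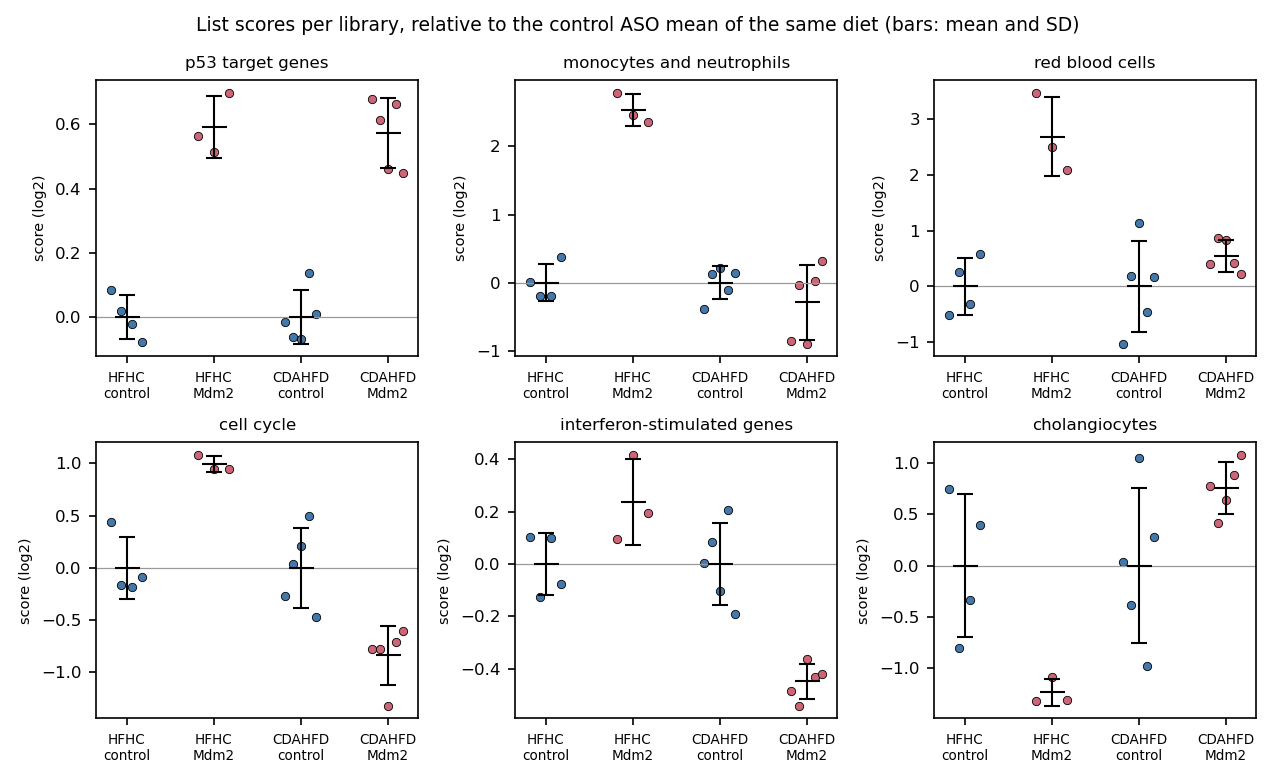
Scores of 6 gene lists per library, as the mean log2 value of the members relative to the control ASO mean of the same diet on the vertical axis, for the 4 groups of diet and ASO, with 1 point per library and bars at the mean and 1 SD. Monocyte and neutrophil, red blood cell and cell cycle scores of the Mdm2 ASO libraries lay above all controls on HFHC, and cell cycle and interferon scores lay under all controls on CDAHFD.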

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

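The tests of blood makeup, of the share of hepatocyte RNA and of the single oligonucleotide were chosen only after the result was seen, whereas the tests of genomic span, of joint scaling and of other groupings of the libraries were set before.

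On HFHC, myeloid and erythroid transcripts such as Itgam and Slc4a1 rose with the Mdm2 ASO, and more residual blood could contribute to that. The monocyte and neutrophil score rose over the T and NK cell score by 1.67 log2 units (pooled SD 0.424), but T and NK cells that reside in the liver could hide an added share, and all 7 red blood cell genes rose, so residual blood cannot be told apart from a response, and perfusion was not analysed here. Alone, a lower hepatocyte RNA share would raise other cell types alike. The monocyte and neutrophil score rose over the cholangiocyte score by 3.77 (pooled SD 0.469). A partial role is open, as endothelial (0.58) and stellate (0.68) medians rose. An effect of the oligonucleotide other than through Mdm2 cannot be told apart from an effect of Mdm2, because the design holds 1 Mdm2 oligonucleotide. Recruitment of myeloid cells after the loss of Mdm2 in hepatocytes may explain the rise and remains a hypothesis, untested here.

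Genes that fell on both diets, 462 in number, had a median genomic span of 28.4 kb among the 459 with a known span, above all 10000 random lists matched on expression and exonic length (percentile 100, median 23.3 kb, highest 28.2 kb). Cleavage of long pre-mRNAs by the oligonucleotide is a candidate explanation for part of them. Genes that fell on CDAHFD but rose on HFHC (30.6 kb, percentile 98.5) or did not pass there (27.0 kb, 97.1) were long too. Those that fell on HFHC alone were short (16.6 kb, 0.11), so length went with falls on CDAHFD. Genes that rose on both diets (18.9 kb, 4.36) argue against calling long genes in either direction. General hepatocyte genes had medians of -0.0459 on CDAHFD (SD over members 0.302) and -0.198 on HFHC (SD 0.279). The genes that fell on both diets had -0.557 and -0.599 but were selected for falling, so this cannot decide on a lower share of hepatocyte RNA. A response to the loss of Mdm2 that lowers long genes remains open and untested.

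For 14 lists the change differed between the diets at the preset correlation of camera, and for 0 with an estimated correlation. The separate scaling of the 2 tables was examined as a source of these calls. With all recovered reads scaled together, 10 of the 14 lists (71.4%) passed again and all 14 kept their direction. Under 50% would point to the scaling and at least 80% away from it, so this stays open. Of the other 4, median differences went from 0.252 to 0.253 (fatty acid oxidation) and 0.151 to 0.137 (fatty acid synthesis). T and NK cells went from -1.04 to -0.857 and red blood cells from -1.63 to -2.14. These 4 also failed with separate scaling and the filter at a value of 5, so scaling need not explain their loss. Depth went with diet, higher on CDAHFD. Depth would not turn signs, and of 28 cell cycle genes 19 rose on HFHC and 11 fell on CDAHFD, which argues against it there. Depth stays open for other lists, and diet cannot be told apart from a batch effect.

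Other groupings of the same libraries show where chance can be excluded. For genes that changed on HFHC the real grouping gave 5331, the most of 35, and the highest other 0. On CDAHFD the real grouping gave 2181 genes, the most of 100, and the highest other 42. For the difference between diets the values were 3832 and 231, again the most of 100. For lists on HFHC chance is open, with 7 of 35 groupings, the real one included, at 21 or more. The highest, 25, put Mdm2 ASO libraries 6-7 and 9 with a control. On CDAHFD 28 of 100 groupings gave at least 15 lists, the highest other 21, and for the difference 37 of 100 gave at least 14, the highest other 24, so chance cannot be excluded for either count. The correlation between the diets, r = 0.0907, was reached in size in 7 of 35 groupings, the real one included, of which 4 were positive and 3 negative, with 0.126 as the highest other, and chance cannot be excluded.

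Single libraries stood apart in 28 of 520 groups tested (5.38%, chance about 1 in 20), with the HFHC Mdm2 ASO group untested. These were 23 of 403 groups for named genes, 5 of 111 for list scores and 0 of 6 for library totals. Gaps to the nearest library are percentages of the group's range of log2 values. Among HFHC controls, replicate 1 was lowest for Mdm2 (84.3%) and Mttp (85.4%) and highest for Mup11 (84.7%), Ifit2 (85.4%), Ckap2 (92.0%) and the cell cycle score (83.9%). HFHC control replicate 5 was lowest for Cox7c (83.0%), replicate 4 highest for Ppef2 (85.7%) and replicate 2 lowest for Muc13 (90.9%). On CDAHFD, control replicate 1 was lowest for Ighm (73.5%), Tgfb1 (78.6%), Vsir (72.6%), Clec4a3 (71.7%) and the MHC class II score (72.1%). Control replicate 2 on CDAHFD was highest for Cp (96.4%) and Igsf11 (81.6%), and replicate 4 was highest for Fcrl5 (100%). Control replicate 3 on CDAHFD was highest for Ecm1 (72.9%) and lowest for Pdia4 (71.6%), Hsd17b13 (74.0%) and the acute phase score (82.8%). Among CDAHFD Mdm2 ASO libraries, replicate 8 was highest for Mlxipl (73.6%) and lowest for the cell cycle score (75.5%), and replicate 9 was lowest for Slc4a1 (95.4%). CDAHFD Mdm2 ASO replicate 10 was lowest for Hsd3b5 (79.3%) and Sec14l5 (73.9%), and replicate 6 was lowest for Ciart (77.5%) and the core clock score (82.7%).

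The effect of the Mdm2 ASO differed between the diets, by the interaction test, for 14 lists at the preset correlation of camera and for 0 with an estimated correlation. Their median differences, CDAHFD minus HFHC, were -3.03 for monocytes and neutrophils, -1.94 for the cell cycle, -1.63 for red blood cells, -1.32 for cytokines, -1.04 for T and NK cells and -0.655 for interferon-stimulated genes. They were 1.91 for cholangiocytes, 1.10 for mitochondrially encoded transcripts, 0.84 for male-biased genes, 0.76 for pericentral hepatocytes, 0.69 for NRF2 and xenobiotic genes, 0.50 for nuclear respiratory chain genes, 0.25 for fatty acid oxidation and 0.15 for fatty acid and triglyceride synthesis.

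Among named genes, 76 of 133 differed between the diets by the same test. Of the genes that rose most on HFHC, the difference was -5.21 for Fcrl5, -4.92 for Itgad, -5.81 for Klra17, -5.54 for Scel, -6.90 for Htra4 and -7.31 for Negr1. These differences depend on how few reads are treated: on CDAHFD, Fcrl5 held 1 read in the controls, and with edgeR its difference was -1.87 (adjusted p = 0.919). With edgeR the differences of Itgad (adjusted p = 0.129) and Scel (adjusted p = 0.124) did not pass either, and with a pseudocount of 0.1 those of Fcrl5 and Scel did not. Over all settings but the estimated correlation, the adjusted p ranged from 0.000546 to 0.919 for Fcrl5, 2.5e-05 to 0.129 for Itgad and 1.7e-05 to 0.124 for Scel. For Fcgr4, Clec4a3, Lipg and Vsir it was -5.23, -5.20, -4.45 and -2.98. Myeloid genes differed by -2.95 (Csf3r), -3.98 (Itgam), -3.54 (S100a8), -4.25 (Itgax), -2.40 (Cd68), -1.90 (Adgre1) and -2.09 (Cd5l). Lymphocyte, red cell and vessel genes differed by -4.16 (Cd79b), -1.51 (Ighm), -3.68 (Slc4a1), -2.001 (Pecam1), -0.86 (Rgs5) and -2.33 (Tgfb1). Slc4a1 on CDAHFD rests on 3 reads in the controls and 4 in the Mdm2 ASO libraries, and its difference did not pass with a pseudocount of 0.1 (adjusted p = 0.104) or with edgeR (adjusted p = 0.156), over a range of 0.000165 to 0.156. Inflammatory and interferon genes differed by -2.45 (Casp1), -3.48 (Ccl4), -0.80 (Icam1), -0.57 (Lbp), -1.08 (Irf7), -1.86 (Gbp2), -0.9998 (Cmpk2), -1.47 (Rsad2), -1.68 (Ifit2) and 0.64 (Stat2). Cell cycle and p53 target genes differed by -2.85 (Mki67), -2.19 (Mcm3), -2.40 (Cdc20), -2.74 (Ccnb1), -3.15 (Eme1), -1.60 (Ckap2), -2.38 (Pmaip1), 0.67 (Pidd1) and 0.41 (Perp). Lipid genes differed by -1.56 (Pparg), -1.50 (Fabp4), -1.58 (Lpl), 1.17 (Mlxipl), 0.92 (Fasn) and 2.03 (Cyp2u1). Respiratory and mitochondrial genes differed by 0.71 (Ndufa1), 0.94 (Ndufa5), 0.83 (Cox5b), 0.90 (Cox7c), 2.10 (ND3) and 2.11 (Lars2). Hepatocyte, bile duct and stress genes differed by 0.49 (Asgr1), 1.10 (Glul), 1.26 (Axin2), 1.46 (Notum), 3.17 (Krt23), 3.57 (Cftr), -2.27 (Slco1a1), -3.14 (Hmox1) and -0.74 (Ppp1r15a). The clock genes Dbp and Tef differed by 1.54 and 0.66. Signaling genes differed by -2.64 (Lyn), -2.17 (Ptpn1), -2.79 (Stap1), -2.35 (Ptpn6), -1.41 (Cd47) and 1.16 (Adcy6). The remaining genes differed by 2.66 (Ephb2), 4.10 (Cyp21a1), -4.37 (Muc13), 0.98 (Gstt2) and 1.02 (Hmcn2).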

How the results depend on the processing

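The filter at a value of 20 and the count of the identical columns as 2 replicates were chosen after the data were seen, and the other alternatives before.

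Mdm2 fell and passed under all alternatives run, with a log2 fold change of -1.51 to -1.27 on HFHC and -1.40 to -1.25 on CDAHFD. No list or named gene reversed a call in any alternative.

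On HFHC, 5331 genes passed, and 2040 did when a 2-fold change was required, stricter by construction. Sample weights gave 8182 genes, edgeR 5335 and DESeq2 5453, and leaving out 1 library gave 3684 (without Mdm2 ASO replicate 9) to 5021. With the identical columns counted as 2 replicates, 6667 genes and 20 lists passed, and with library 6-7 left out, 4857 genes did. Quantile normalization moved the median of all genes by -0.132 on HFHC and of the difference by 0.122, and of the genes that passed on HFHC 40.0% rose, against 55.0% with the deposited scaling.

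On CDAHFD, 2181 genes passed, and 394 did at 2-fold or more. Moderation without a mean trend (eBayes) gave 1424 genes, edgeR 2186 and DESeq2 2956. Leaving out 1 library gave 1232 (without control ASO replicate 2) to 2283 genes.

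For the difference between diets, 3832 genes passed, 5838 with sample weights and 5096 with separate fits per diet. A replicate block, which pairs mice that share only a number, gave 3033, of which 2665 also passed without it. Pairs with a shared number had correlations from -0.178 to 0.204 and none matched its own number best. The correlation of the fold changes, 0.0907, was 0.0689 with sample weights, 0.122 with the filter at 20, 0.120 with edgeR and 0.117 with DESeq2. Without single CDAHFD libraries it ranged from 0.0509 (without Mdm2 ASO replicate 7) to 0.122 (without Mdm2 ASO replicate 8). For sample weights, eBayes without a trend, single libraries and the correlation, the cause was not tested.

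Gene lists depended on the correlation between their genes: 21 passed on HFHC, 15 on CDAHFD and 14 for the difference at the preset correlation of camera, and 0, 0 and 0 with an estimated correlation, where 2, 3 and 2 had an unadjusted p under 0.05. Over all other alternatives, 14 of the 21, 8 of the 15 and 10 of the 14 passed every time. Most calls ended for endoplasmic reticulum stress (0.00918 to 0.325, 9 of 20 alternatives) and interferon-stimulated genes (0.00196 to 0.294, 8 of 20) on HFHC, for mitochondrially encoded transcripts (0.00167 to 0.247, 8 of 22) and the acute phase (0.00553 to 0.120, 6 of 22) on CDAHFD, and for fatty acid synthesis (5.1e-04 to 0.366, 15 of 29) and oxidation (0.00488 to 0.604, 14 of 29) in the difference. Of the lists that lost a call when 1 library was left out, those on HFHC did so without Mdm2 ASO replicates 6-7 or 9 or control replicates 2, 4 or 5, and the clock on CDAHFD did so without Mdm2 ASO replicate 10.

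Named genes kept their calls in all alternatives run for 102 of 114 on HFHC, 50 of 75 on CDAHFD and 58 of 76 for the difference. On HFHC, Ppef2 lost its call in 13 of 19 alternatives and Ciart in 12 of 20. On CDAHFD, Mlxipl lost its call in 12 of 22 alternatives, Lpl in 11 and Pdk4, Abcb4 and Mir6358 in 9 each. Leaving out CDAHFD control ASO replicate 2 ended 17 gene calls and leaving out replicate 4 ended 12. For the difference, Lbp lost its call in 18 of 31 alternatives, Ighm in 16 and Tef in 14.

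Depth of 17.8 to 31.5 M reads limits genes with few reads, such as Fcrl5 on CDAHFD with 1 read in the controls.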

Other observations

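The limma and camera tests here are those fixed before the data were examined, while Fcgr4, Lipg, Vsir, Clec4a3, Opa1, Hmcn2, Gria3 and Igsf11 were chosen after their values were seen.

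Fcgr4, which encodes a receptor for immunoglobulin G on monocytes and macrophages, had the smallest p on HFHC and rose from 190 ± 24.8 to 11225 ± 671, a 59.3-fold change (log2 fold change 5.89, SE 0.10, adjusted p = 5.4e-09), while it did not pass on CDAHFD (0.66, adjusted p = 0.399). Lipg, the endothelial lipase, rose from 190 ± 30.1 to 4399 ± 277 (log2 fold change 4.54, SE 0.12, adjusted p = 7.2e-08), and Vsir, the checkpoint protein VISTA of myeloid cells, rose from 237 ± 10.0 to 1631 ± 76.2 (log2 fold change 2.78, SE 0.08, adjusted p = 7.2e-08). Clec4a3, a C-type lectin of monocytes, rose from 63.4 ± 11.8 to 2395 ± 217 (log2 fold change 5.24, SE 0.15, adjusted p = 7.2e-08). On CDAHFD, Lipg, Vsir and Clec4a3 did not pass (0.08, adjusted p = 0.867, -0.20, adjusted p = 0.608 and 0.04, adjusted p = 0.956).

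Opa1, the dynamin-related GTPase that fuses inner mitochondrial membranes, fell from 1385 ± 201 to 402 ± 49.6 on CDAHFD (log2 fold change -1.78, SE 0.12, adjusted p = 2.9e-06) and from 1313 ± 73.5 to 482 ± 72.2 on HFHC (log2 fold change -1.45, SE 0.11, adjusted p = 8.3e-06). Hmcn2, an extracellular matrix protein, rose from 375 ± 36.8 to 1520 ± 321 on CDAHFD (log2 fold change 2.00, SE 0.13, adjusted p = 2.9e-06) and by 0.98 on HFHC (adjusted p = 0.00654). Gria3, a glutamate receptor subunit, rose from 116 ± 33.9 to 694 ± 140 on CDAHFD (log2 fold change 2.59, SE 0.20, adjusted p = 1.3e-05) and by 2.34 on HFHC (adjusted p = 0.00224). Igsf11, an immunoglobulin-like adhesion molecule, fell from 1547 ± 129 to 718 ± 76.5 on CDAHFD (log2 fold change -1.11, SE 0.09, adjusted p = 2.3e-05) and by 1.09 on HFHC (adjusted p = 2.9e-05). Alb, the albumin gene, took 9.59% of all counts in HFHC Mdm2 ASO library 6-7, 5.66% in library 9 and 5.92% in library 10. In the HFHC control libraries it took 4.11 to 4.73%, under every Mdm2 ASO library.

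Lists that did not pass on HFHC are given here with their limma counts. Gluconeogenesis genes gave 2 increases and 3 decreases among 15, with a median of -0.19, a mean of 0.21 and a test that pointed down (camera adjusted p = 0.512). Acute phase genes gave 3 increases and 6 decreases among 22 (median -0.17, camera adjusted p = 0.189), Cp among the latter (-0.65, adjusted p = 0.00219). Core clock genes gave 1 increase and 1 decrease among 14, with a median of 0.04 under a test that pointed down (camera adjusted p = 0.891). Male-biased genes gave 6 increases and 5 decreases among 19, with a median of 0.19 under a test that pointed down (camera adjusted p = 0.891). Female-biased genes had 0 of 12 pass by limma, with 2 at an unadjusted p under 0.05 and a median of 0.03 under a test that pointed down (camera adjusted p = 0.891). Periportal markers gave 1 increase and 2 decreases among 14 (median 0.19, camera adjusted p = 0.891), and white adipose genes 2 decreases among 5 (median -0.30, camera adjusted p = 0.296). Exocrine pancreas had 1 gene that could be tested (log2 fold change -0.30), skeletal muscle 4 (median 0.63) and gut epithelium 3, all 3 of which fell (median -0.65), too few for the list test.

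On CDAHFD, cholesterol synthesis genes had 0 of 25 pass by limma and 2 at an unadjusted p under 0.05 (median 0.18, camera adjusted p = 0.332). VLDL secretion genes gave 3 increases and 4 decreases among 26 (median -0.15, camera adjusted p = 0.324). Gluconeogenesis genes gave 1 increase among 15 (median 0.02, camera adjusted p = 0.469), and matrix genes 2 decreases among 32 (median -0.05, camera adjusted p = 0.616). MHC class II genes had 0 of 7 pass by limma (median -0.20, camera adjusted p = 0.190), endoplasmic reticulum stress genes 0 of 20 (median 0.02, camera adjusted p = 0.843) and T and NK cell markers 0 of 16 (median -0.19, camera adjusted p = 0.550), with 0, 4 and 0 members at an unadjusted p under 0.05. Female-biased genes gave 1 decrease among 13 (median -0.11, camera adjusted p = 0.677), pericentral markers 2 increases among 14 (median 0.19, camera adjusted p = 0.140) and periportal markers 1 increase and 2 decreases among 14 (median 0.003 under a test that pointed down, camera adjusted p = 0.843). Kupffer cell markers gave 1 decrease among 11 (median -0.16, camera adjusted p = 0.307), and red blood cell genes had 0 of 6 pass by limma, with 1 at an unadjusted p under 0.05 (median 0.54, camera adjusted p = 0.129). Exocrine pancreas, white adipose tissue, skeletal muscle and gut epithelium had 1, 4, 3 and 4 testable genes, too few for the list test, of which 1 adipose gene fell and 1 gut gene rose.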
